A study of Homo sapiens with 8 samples.

How the data were processed

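The series measured RNA of cultured human epidermal keratinocytes on Affymetrix arrays of short oligonucleotide probes, grouped in probe sets. Per the labels' protocols, the cells grew in a serum-free keratinocyte medium with EGF and bovine pituitary extract, AG1478 was added to the treated cultures, total RNA was purified with DNase treatment, and its quality was checked on a gel and by absorbance before labelling with biotin. AG1478, a tyrphostin, is a small molecule that inhibits the tyrosine kinase of the EGF receptor (EGFR). The labels put 4 arrays in the untreated arm and 4 in the AG1478 arm, 1 of each at 1, 4, 24 and 48 h. The labelled time pairs the arrays. The labels do not say whether arrays came from separate cultures or donors, so p-values measure only the spread between these arrays, which may be partly technical. A dose was not used here.

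The deposited values are linear probe set intensity, with no log transform. The software that made them is not given in the sources used here. On every array the mean of the values without the lowest and highest 2% was about 150.1, a scaling read from the values and not stated in the labels, while the log2 array medians differed by up to 0.68. The table gave no detection calls. Precision is limited by the number of arrays.

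From there, values were taken to log2(value + 1) and quantile normalized, because the medians differed by more than the limit of 0.15 set in advance. A fold change is therefore on the log2(value + pseudocount) scale, where the pseudocount shrinks the change of dim genes. Values in the noise can also inflate a change. The late fall of GPR176 was 32.3-fold as measured, against at least 2.44-fold with the background described below. Of 22277 probe sets, 62 were controls and left the tests, 19064 had 1 gene symbol, 1043 had several and 2108 had none in the platform annotation used here. Probe sets with several symbols or none were not named. Gene identifiers led to an updated symbol in 0 cases. Each of the 11963 genes was represented by its probe set with the highest mean over the 8 arrays, which was a choice among several for 4310 genes. The lowest 40% of genes by mean left the tests, and 7178 genes were tested.

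Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend and robust settings), with Benjamini-Hochberg adjustment at 0.05. The treatment effect over all times had time as a factor and 3 residual degrees of freedom. The early effect (1 and 4 h) and the late effect (24 and 48 h) came from a fit with time as a factor and a treatment term for each phase, with 2 residual degrees of freedom, and the late minus early effect was the contrast of these terms. Change with culture time in untreated cells was tested on means of phase by treatment without the time factor (4 residual degrees of freedom). At single time points there is 1 array per arm and no test. The design, the gene lists and the rule for named genes were set before the data were examined. So were the alternatives, except the fits with only the trend or only the robust setting.

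The 26 gene lists comprised 21 functional lists and 5 lists of markers of other cell types, and 23 had at least 5 tested genes. They were tested with camera (preset correlation 0.01), with an estimated correlation beside it, and with fry, each adjusted over the 23 lists. At each time, a list's median was placed among 10000 random lists of the same size matched on mean level. Genes were named by rule. For each tested effect these were the 10 largest rises and 10 largest falls past the threshold with the same sign at every time of the effect, or, where fewer than 5 passed in a direction, the 10 largest mean differences, given as values that did not pass. Up to 4 members of each list with the largest absolute late difference, a fixed set of EGFR target genes, and the 5 highest and 5 lowest differences at each time were also taken. The results print only part of the genes taken by this rule. Some members of the lists had no probe set with a single symbol and were not analysed here.

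Background was set after the data were seen, as the 95th percentile of 27 probe sets for bacterial genes that had not been spiked in, on each array. Where all arrays of the dimmer group lay under it, the fold is given as at least N-fold, the mean of the brighter group over the mean of the higher of background and measured value on each array of the dimmer group. Such a bound is for the mean over the times of the effect and carries no error, and a single time can lie under it. For the late minus early effect, which has no such bound, the contrast was also computed with each value under background raised to it.

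The tests were tried on simulated data with 200 changed genes among 7178. These had the same spread early and late and, for the test over all times, the same change at every time. The real data differ in both respects, so recovery in them may differ. The late test recovered 15.8% of genes changed by 1 log2 unit, 63.6% of those changed by 2 and 97.4% of those changed by 4. The early test recovered 18.4%, 71.4% and 92.6%, the test over all times 43.3%, 79.7% and 98.4%, the late minus early test 1.6%, 32.2% and 90.9%, and the culture time test 27.1%, 74.0% and 91.2%. The 24 and 48 h differences varied more than the 1 and 4 h ones (SD across genes of 1.37 for the 24 h minus the 48 h difference, 0.86 for 1 h minus 4 h). False calls in these simulated data numbered 12 of 138 late, 6 of 120 early, 3 of 150 over all times, 13 of 103 late minus early and 12 of 144 culture time calls, above the level of 0.05 for late, late minus early and culture time. In 20 simulations with this inequality and no changed gene, the late test called at most 7 genes (median 1).

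Alternatives were the values as deposited, arrays centred on their medians, a pseudocount of 16, no filter, a filter at 60%, the mean of all probe sets, eBayes without trend and robust settings, array weights, a fit on only the 24 and 48 h arrays, other designs, and leaving out each time pair. List calls were counted on unrounded adjusted p-values. Tables were prepared with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.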

Results

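Transcript levels were compared between untreated cultured human epidermal keratinocytes and cells given AG1478, an inhibitor of the EGFR tyrosine kinase, at 1, 4, 24 and 48 h, with 1 array per arm at each time and 8 arrays in all. The question was which transcripts depend on EGFR activity and when. The number of arrays limits the precision. The AG1478 24 h array stood apart in RNA quality: its ratio of 3' to 5' signal was 9.39 for ACTB and 5.69 for GAPDH, against 0.939 to 1.48 and 0.924 to 1.18 on the other 7 arrays, and its spike-in controls had a geometric mean intensity of 2796 against 890.0 to 1303. The untreated 48 h array had an 18S ribosomal RNA signal of 1929, against 52.8 to 542 on the others. Counts without the 24 h or the 48 h pair are given for the gene lists with late calls. In such a fit the lone late pair borrows the spread of the early pairs, which varied less, and more genes pass in all. These counts therefore cannot show that a list withstands the loss of a pair.

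The late comparison asked what differed after 1 to 2 days of inhibition. Of 7178 genes, 415 passed in limma with Benjamini-Hochberg adjustment, 183 higher and 232 lower, and 387 of the 415 changed at least 2-fold. All 415 had the same sign at 24 and 48 h. The test itself requires this, because a difference between the 2 times counts as spread, so it is not separate evidence. Rises were met in 8 of 25 early differentiation, 9 of 23 cornified envelope, 10 of 35 interferon-response and 3 of 8 antimicrobial genes, and falls in 12 of 26 ERK feedback, 14 of 33 wound activation and 9 of 24 unfolded protein response genes. Each of these lists passed in camera at its preset correlation, and none with an estimated correlation (adjusted p = 0.27 or more). This loss did not come from correlation between genes alone. The early differentiation list had an estimated correlation of 0.005, under the preset 0.01, yet its unadjusted camera p went from 4.5e-08 to 0.029. CXCL14, an epithelial chemokine, was at least 123-fold higher (limma with Benjamini-Hochberg, adjusted p = 0.0029), IGFBP3, an insulin-like growth factor binding protein, at least 155-fold (adjusted p = 0.003), and DSC1, a desmosomal cadherin of differentiated layers, at least 70.7-fold (adjusted p = 0.0022). The cytochromes CYP1A1 and CYP1B1 were at least 44.9-fold and 18.0-fold higher, and LY6D at least 27.0-fold. These bounds are for the mean of 24 and 48 h and need not hold at each time. The measured log2 difference of CYP1A1 was 4.45 at 24 h and 8.78 at 48 h, with a mean of 6.61 ± 1.32. PTGES, a prostaglandin E synthase, rose by 5.38 ± 0.85 (log2, SE, 2 pairs) on the probe set used, while its other probe set gave 0.58. KRT13 rose by 5.0 ± 0.39 and CLIC3 by 4.81 ± 0.71. TMT1A was at least 14.2-fold higher on the probe set used, while its other probe set gave -0.50. Of 141 late calls with more than 1 probe set above the filter, 24 had a probe set of opposite sign and 59 had one with under 50% of the log2 difference on the probe set used. In 45 of the 415 calls both arrays of the dimmer arm lay under background. A single dim array lay under it for PTGES, CLIC3, CALML5, COL5A1, EVPL and KLK7 (untreated 24 h), G0S2, MMP1, DUSP4, HBEGF, CCNB1, MCM6 and RRM2 (AG1478 48 h), and PLAT and VEGFA (AG1478 24 h), so the sizes given for these genes are uncertain.

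Among the falls, TFPI2, a protease inhibitor, was at least 48.1-fold lower on the probe set used (limma with Benjamini-Hochberg, adjusted p = 4.4e-05), while its other probe set gave a log2 difference of -2.28. DUSP6, a phosphatase of ERK, was at least 17.7-fold lower and DCBLD2 at least 14.0-fold lower. G0S2, an inhibitor of lipolysis, had a log2 difference of -6.63 ± 0.40 (adjusted p = 0.00036 in limma with Benjamini-Hochberg) and MMP1, interstitial collagenase, of -5.31 ± 0.37. TGM2 was at least 5.86-fold lower, ETV4 4.68-fold, DNAJC3 2.77-fold, NAV3 2.58-fold and GPR176 2.44-fold, each as a lower bound. Of the 3 probe sets of TGM2 the weakest gave -0.25, against -4.68 on the one used. With only the 24 and 48 h arrays 357 genes passed, 313 of them shared, and in limma with Benjamini-Hochberg adjustment the calls of DNAJC3 (adjusted p = 0.066), NAV3 (adjusted p = 0.082) and GPR176 (adjusted p = 0.094) were lost. With eBayes lacking the intensity trend and the robust setting, 0 genes passed and 1328 had an unadjusted p under 0.05. The count was 995 without the 24 h pair (321 higher, 674 lower) and 1290 without the 48 h pair (624 and 666), fits in which a lone late pair borrows the spread of the early pairs. Arrays centred on their medians gave 86 higher and 226 lower, a share of 27.6% higher against 44.1%, with a median of all genes of -0.22.

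**Figure D1:**
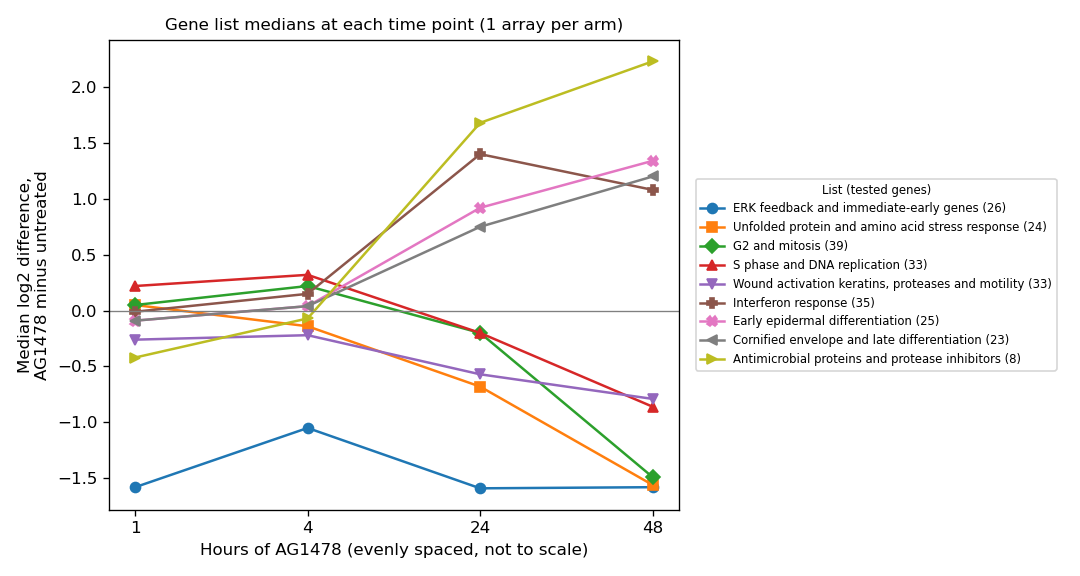
Median log2 difference (AG1478 minus untreated, y axis) of 9 gene lists at 1, 4, 24 and 48 h (x axis, evenly spaced), with 1 array per arm at each time, so no error can be drawn. The median of ERK feedback genes lies at -1.58, -1.05, -1.59 and -1.58, while that of G2 and mitosis genes lies at -0.20 at 24 h and -1.49 at 48 h.

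ERK feedback and immediate-early genes, which are induced by growth factor signalling, served as the check of the inhibitor. Late, 12 of 26 tested members fell and 2 rose (18 and 2 adjusted over the list alone), with a median of -1.51, or -1.46 with members near background at their bound. Falls included DUSP6, ETV4, ETV5, at least 6.46-fold lower, and SPRY2, at least 1.90-fold lower, which lost its call with only the 24 and 48 h arrays (limma with Benjamini-Hochberg, adjusted p = 0.18). DUSP4 fell by 4.01 ± 0.59 (log2, SE) and FOSL1, a subunit of AP-1, by 3.36 ± 0.43. The risers were DUSP1 (2.06 ± 0.45) and ATF3, a stress-induced transcription factor, at least 9.91-fold higher. The list was lower in camera (adjusted p = 2.3e-06), and adjusted p = 0.27 with an estimated correlation. Without the 24 h pair 13 fell, and without the 48 h pair 14. EGR1 (-1.50 ± 0.49), FOS, MYC (-1.08 ± 0.34) and CCND1 (-1.40 ± 0.43) did not pass. With only the 24 and 48 h arrays FOS (adjusted p = 0.0069) and MYC (adjusted p = 0.043) did, in limma with Benjamini-Hochberg adjustment. In the fixed set of EGFR target genes, SPRY4 (-2.03 ± 0.42) and PHLDA1 (-2.67 ± 0.43) also fell late. TGFA (-1.25 ± 0.30) and IER3 (0.43 ± 0.33) did not pass, and IER3 had differed by -2.37 at 1 h. Of the EGFR family and ligands, 1 of 10 fell (4 fell and 1 rose adjusted over the list alone), HBEGF, a ligand, by 2.13 ± 0.40. EGFR itself differed by -0.48 ± 0.20 on the probe set used, without passing. The 4 probe sets of EGFR above the filter ranged from -2.76 to -0.47, so the size of its change is uncertain. Camera gave the EGFR family list adjusted p = 0.09. In the EGFR list 2 fell without the 24 h pair, and 4 fell and 1 rose without the 48 h pair.

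Of 25 early epidermal differentiation genes, 8 rose and 1, the Notch ligand JAG1, fell (12 and 1 adjusted over the list alone). Examples besides DSC1, LY6D and KRT13 were CALML3 (2.89 ± 0.50), FABP5, a fatty acid binding protein (2.57 ± 0.31), and KRT10, a suprabasal keratin (1.75 ± 0.40). CALML5 (4.03 ± 1.20) did not pass. The median was 1.23 (camera adjusted p = 5.2e-07; adjusted p = 0.27 with an estimated correlation), and 11 rose without the 24 h pair and 10 without the 48 h pair. Of 23 cornified envelope and late differentiation genes, 9 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.88. These included the crosslinked precursors SPRR1A (3.34 ± 0.28), SPRR1B (3.02 ± 0.27), IVL (2.49 ± 0.44) and EVPL (3.21 ± 0.67), and the protease KLK7 (3.58 ± 0.73). This list had camera adjusted p = 3.4e-05 and adjusted p = 0.27 with an estimated correlation, and 12 rose without the 24 h pair and 9 without the 48 h pair. In the barrier lipid list 1 of 13 rose, the ceramidase ASAH1 (3 adjusted over the list alone), with a median of 0.46, or 0.02 with members near background at their bound, and camera adjusted p = 0.14. The probe sets of ASAH1 ranged from -0.93 to 1.4, and its call was lost with only the 24 and 48 h arrays (limma with Benjamini-Hochberg, adjusted p = 0.056). Without the 24 h pair 3 rose (median 0.29), and without the 48 h pair 1 (median 0.06).

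Of 8 antimicrobial genes, 3 rose (5 adjusted over the list alone), namely S100A8 (3.95 ± 0.29) and S100A9 (3.74 ± 0.32), which form calprotectin, and ADM (2.76 ± 0.24). The median was 1.5 (camera adjusted p = 5.2e-05; adjusted p = 0.27 with an estimated correlation). Leaving out the 24 h or the 48 h pair gave 4 rises each. Of 35 interferon-response genes, 10 rose and 0 fell (17 and 1 adjusted over the list alone), with a median of 1.21. GBP1 (3.35 ± 0.42), IFIT1 (3.19 ± 0.36), IFIT3 (2.84 ± 0.30) and MX1 (2.30 ± 0.28) were among them. The list had camera adjusted p = 6.5e-10 and adjusted p = 0.27 with an estimated correlation, and 12 rose without the 24 h pair and 14 without the 48 h pair. Of 18 chemokine and cytokine genes, 5 rose and 2 fell, the same counts adjusted over the list alone. CXCL14, PTGES and TNFSF10 (2.29 ± 0.45) rose, and the interleukins IL1A (-3.27 ± 0.49) and IL1B (-1.51 ± 0.22) fell. Camera gave adjusted p = 0.013 for this list, and adjusted p = 0.31 with an estimated correlation. The counts were also 5 and 2 without either late pair, and without the 48 h pair the list had adjusted p = 0.067 in camera.

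Of 33 wound activation genes, 14 fell and 4 rose (16 and 5 adjusted over the list alone), with a median of -0.66. Besides MMP1, the stromelysin MMP10 (at least 6.35-fold lower), the plasminogen activator PLAT (-3.28 ± 0.58), the collagen receptor subunit ITGA2 (-2.93 ± 0.39) and VEGFA (-2.31 ± 0.44) fell. KRT16, a keratin of activated and suprabasal cells, rose by 3.70 ± 0.23. Camera gave adjusted p = 0.0024, and adjusted p = 0.31 with an estimated correlation. Leaving out the 24 h pair gave 18 falls, and leaving out the 48 h pair 15.

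Among 24 genes of the unfolded protein and amino acid stress response, 9 fell and 0 rose (13 and 2 adjusted over the list alone), with a median of -1.19. They included the chaperones HSP90B1 (-3.76 ± 0.32) and HSPA5 (-2.09 ± 0.21), HERPUD1 (-2.19 ± 0.24) and the serine synthesis enzyme PSAT1 (-2.34 ± 0.45). The other probe set of HSP90B1 gave -1.03. Camera gave adjusted p = 4.2e-05, and adjusted p = 0.27 with an estimated correlation. Without the 24 h pair 14 fell and 1 rose (median -1.56), and without the 48 h pair 11 fell (median -0.68).

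Cell cycle genes had lower medians with few single calls. On the AG1478 48 h array BUB1B, AURKA, TOP2A, CDC45 and MCM10 lay under background, so the size of the fall at 48 h is uncertain. Of 39 G2 and mitosis genes 3 fell, CCNB1 (-1.95 ± 0.35), UBE2C and PRC1, also 3 adjusted over the list alone, with a median of -0.91. This list had camera adjusted p = 4.8e-06 and adjusted p = 0.34 with an estimated correlation. The count of falls was 1 with only the 24 and 48 h arrays, 18 without the 24 h pair (median -1.49) and 6 without the 48 h pair (median -0.20), where the list no longer passed (camera adjusted p = 0.067). Of 33 S phase genes 4 fell (6 adjusted over the list alone), among them RRM2, a subunit of ribonucleotide reductase (-1.98 ± 0.39), and MCM6 of the replicative helicase (-1.72 ± 0.36). Their median was -0.67, or -0.57 with members near background at their bound (camera adjusted p = 8.2e-05; adjusted p = 0.34 with an estimated correlation), and 10 fell without the 24 h pair (median -0.86), 9 without the 48 h pair (median -0.20) and 3 with only the 24 and 48 h arrays. Of 17 cell cycle inhibitors 3 rose, CDKN1A (1.27 ± 0.23), GADD45B and KLF4 (4 rose and 1 fell adjusted over the list alone), and camera gave adjusted p = 0.089. Leaving out the 24 h pair gave 4 rises, and leaving out the 48 h pair 3 rises and 2 falls. Of 25 ribosome biogenesis genes 2 fell, RRS1 and DDX21, also 2 adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.34 with an estimated correlation), and the list did not pass in camera without the 24 h pair (adjusted p = 0.12) or the 48 h pair (adjusted p = 0.061), where 2 and 4 genes fell. With only the 24 and 48 h arrays 0 fell, with adjusted p = 0.1 for RRS1 and 0.062 for DDX21 in limma with Benjamini-Hochberg adjustment.

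The other functional lists were not called by camera. Of 22 basal layer genes 3 rose, IGFBP3 among them, and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.95), with the hemidesmosome integrin ITGB4 (-2.33 ± 0.26) lower and KRT15 (1.26 ± 0.24) higher. Of 19 oxidative stress and xenobiotic genes 4 rose, among them CYP1A1 and CYP1B1, and 3 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.81). Single genes passed in the glycolysis list (SLC2A1, the glucose transporter, 2.5 ± 0.21), the heat shock list (HSPB1, 2.71 ± 0.15, and HSPD1, -0.69 ± 0.15), the cholesterol list (INSIG1, -1.95 ± 0.29), the apoptosis list (BCL2L1, -1.88 ± 0.36) and the antigen presentation list (PSMB9, 1.06 ± 0.24). Their camera adjusted p was 0.95, 0.69, 0.47, 0.94 and 0.081 in that order. Adjusted over the list alone, 1 rose and 1 fell of glycolysis, 1 and 2 of heat shock, 0 and 2 of cholesterol, 0 and 1 of apoptosis and 3 and 1 of antigen presentation genes. Without the 24 h pair 3 basal layer genes rose and 4 fell, and without the 48 h pair 4 and 4. In the same order the counts were 4 and 5, then 4 and 6, for oxidative stress, 1 and 2, then 1 and 3, for glycolysis, 1 and 1, then 1 and 2, for heat shock, 0 and 2, then 0 and 4, for cholesterol, 2 and 2, then 0 and 2, for apoptosis, and 2 and 0, then 5 and 2, for antigen presentation genes. With only the 24 and 48 h arrays the calls of HSPD1 (adjusted p = 0.11) and PSMB9 (adjusted p = 0.1) were lost in limma with Benjamini-Hochberg adjustment, and 0 oxidative stress genes fell. Median and mean differed in sign for apoptosis (0.08 and -0.11), glycolysis (-0.05 and 0.03), heat shock (-0.24 and 0.03) and oxidative stress genes (-0.03 and 0.49). Across the 23 lists, camera called 12 late, 5 higher and 7 lower, fry called 11, and 0 held with an estimated correlation. Without the 48 h pair camera called 8.

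Markers of endothelial cells, leukocytes and melanocytes were mostly dim. In contrast, 4 of 15 fibroblast markers and 5 of 9 markers of Merkel or gland cells lay above background on all 8 arrays. Some were bright in untreated cells, with VIM at 12.89 to 13.07 and KRT18 at 12.73 to 13.26 (normalized log2 intensity). Whether these transcripts came from the keratinocytes themselves or from other cells was not tested, so they do not show that other cell types were present. Endothelial and leukocyte markers had 0 tested genes, and the melanocyte list had 1, MC1R (0.02 ± 0.66). Of 6 fibroblast markers COL5A1 rose (3.24 ± 0.59) and VIM fell (-2.29 ± 0.32), with camera adjusted p = 0.81. Here 1 rose and 2 fell without the 24 h pair, and 1 and 1 without the 48 h pair. Of 5 markers of Merkel, sebaceous or sweat gland cells KRT18 fell (-2.52 ± 0.21), and camera gave this list adjusted p = 0.033, and adjusted p = 0.34 with an estimated correlation. That list did not pass in camera without the 24 h pair (adjusted p = 0.16; 1 rose and 3 fell) or the 48 h pair (adjusted p = 0.056; 2 fell).

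**Figure D2:**
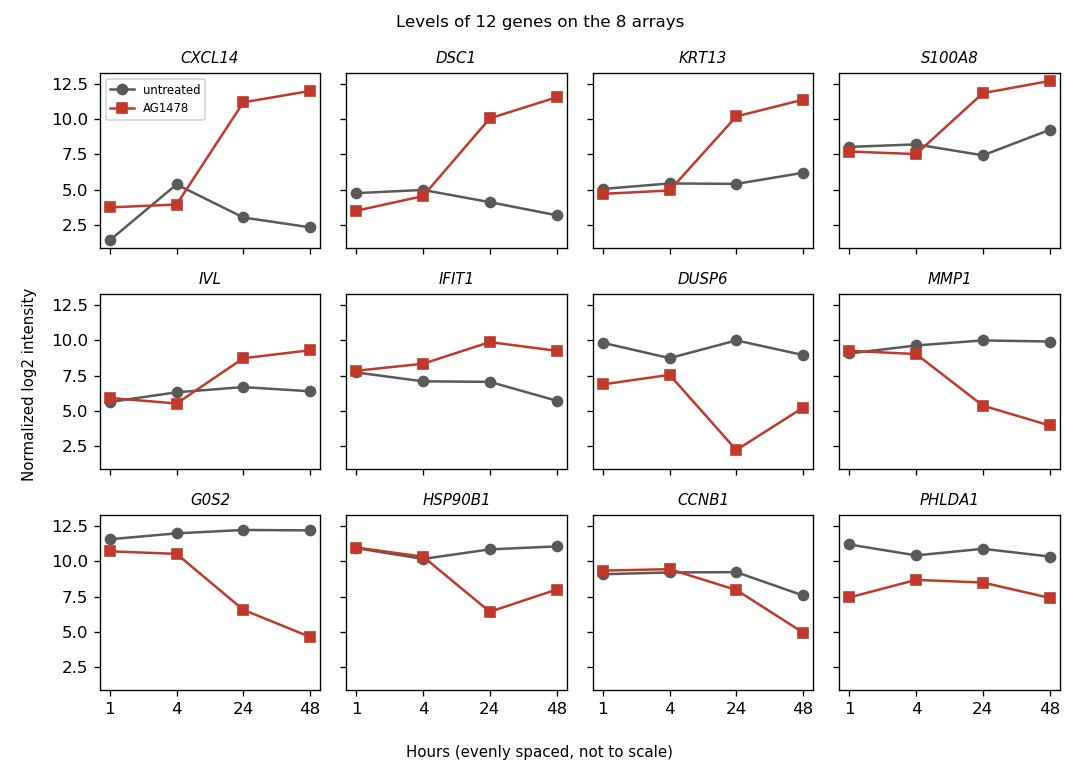
Normalized log2 intensity (y axis) of 12 genes on the 8 arrays by time (x axis, hours, evenly spaced), with gray circles for untreated and red squares for AG1478, 1 array per point and no error. CXCL14 reads 11.21 at 24 h and 12.02 at 48 h with AG1478, against 3.02 and 2.32 untreated.

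The early comparison asked what differed within the first hours. In limma with Benjamini-Hochberg adjustment 0 genes passed, 198 had an unadjusted p under 0.05 where 359 would be met by chance, and the smallest adjusted p was 0.143. The early test shares its estimate of spread with the late pairs, whose differences varied more. The SD across genes was 1.37 for 24 h minus 48 h and 0.86 for 1 h minus 4 h. The early test is therefore strict, and a count under that met by chance does not show that few genes responded early. The 10 largest negative fitted values follow, and none of them passed. HBEGF differed by -3.10 ± 0.40 (log2, SE), TRIB1 by -2.78 ± 0.37, MAFF by -2.78 ± 0.54 and PHLDA1 by -2.76 ± 0.43. MAP3K6 differed by -3.31 ± 1.09, with its AG1478 1 h value under background. As lower bounds, ARHGAP19 was 3.38-fold, FARP2 2.11-fold, MYL9 1.96-fold and CRYBG2 1.86-fold lower, and FOS, an immediate-early transcription factor, 2.52-fold, with both of its 4 h values under background. Positive values included IFIT2 (2.37 ± 0.92, with its untreated 1 h value under background), FBXL15, at least 2.51-fold higher, and CLIC3, at least 1.60-fold higher. None of these passed. The ERK feedback list was lower in camera with a median of -1.42 (adjusted p = 2e-16; adjusted p = 0.61 with an estimated correlation), with 13 falls adjusted over the list alone. The wound activation list was lower (adjusted p = 0.00073; adjusted p = 0.74 with an estimated correlation) and the S phase list higher (adjusted p = 0.037; adjusted p = 0.74 with an estimated correlation). fry called 0 lists. Without the 24 h pair 32 genes passed and without the 48 h pair 34, most of them lower (28 and 30), and with array weights 29. The count at an unadjusted p under 0.05 was 585 and 579 in the fits without the 24 h and the 48 h pair, and 98 and 92 without the 1 h and the 4 h pair.

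The late minus early contrast tested which effects differed between phases. In limma with Benjamini-Hochberg adjustment 40 genes passed, 21 with a higher and 19 with a lower late effect (21 and 11 on the values as deposited, 2 and 7 on phase means without the time block, 167 and 341 without the 24 h pair, 328 and 357 without the 48 h pair). Higher late effects with values above background on all 8 arrays included those of S100A8 (4.45 ± 0.41), KRT16 (3.94 ± 0.33) and SPRR1A (3.81 ± 0.39), and lower ones that of HSP90B1 (-3.86 ± 0.45), whose probe sets differed in size. The effects that follow rest in part on values under background. With those raised to it, each of these effects kept its sign. The log2 contrast was then 7.26 for CXCL14, 6.26 for DSC1, 5.30 for KRT13 and 4.12 for CRYAB, a small heat shock protein. It was -5.32 for TFPI2, -5.07 for G0S2, -4.57 for DCBLD2, -4.35 for MMP1, -2.98 for LPXN, -2.78 for TGM2 and -1.76 for ETV4. These raised contrasts have no error or test. The remaining calls had no value under background, so raising could not move them. The ERK feedback list did not pass in this contrast (median -0.26, camera adjusted p = 0.61). Camera called 8 lists, 4 higher (early and late differentiation, interferon and antimicrobial genes) and 4 lower (mitosis, S phase, unfolded protein and Merkel or gland markers), with adjusted p = 0.28 or 0.42 with an estimated correlation. The count was 508 without the 24 h pair, 685 without the 48 h pair, 16 without the 1 h pair, 22 without the 4 h pair and 0 without the trend and robust settings.

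Over all 4 times together 0 genes passed in limma with Benjamini-Hochberg adjustment, and 661 had an unadjusted p under 0.05, where 359 would be met by chance. That count was 428 without the 24 h pair and 359 without the 48 h pair. In this test a change present at some times only counts as spread, so 0 calls do not show that no gene responded. PHLDA1 had the smallest adjusted p, 0.075, with a difference of -2.71 ± 0.31 and lower values at 4 of 4 times. MAFF (-2.76 ± 0.37), SPRY2 (-2.81 ± 0.67) and FOS were lower at all 4 times, and CLIC3 (3.73 ± 0.60), ID3 (2.18 ± 0.46) and BEX1 (2.99 ± 0.62) higher, none of them passing. MAFF, SPRY2, FOS, CLIC3 and BEX1 lay under background on some arrays, so their sizes are uncertain. Camera called 11 lists, 6 higher and 5 lower, led by the ERK feedback list (median -1.63, adjusted p = 4e-13; adjusted p = 0.23 with an estimated correlation), the 1 list fry called. With an estimated correlation 0 lists were called, and camera at its preset correlation called 3 without the 48 h pair and 8 without the 24 h pair. A fit on arrays centred on their medians called 24 genes, 23 of them lower.

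At single times, without replicates, 634 genes differed at least 2-fold at 1 h (199 higher, 435 lower), 610 at 4 h (283 and 327), 2140 at 24 h (1146 and 994) and 1890 at 48 h (739 and 1151). The correlation of differences across genes, which are not independent replicates, was 0.34 between 24 and 48 h and 0.12 between 1 and 4 h. Of the genes 2-fold different at 24 h, 68.4% had the same sign at 48 h. The ERK feedback median lay below all 10000 matched random lists at each time. At 4 h CYP1A1 stood at 7.69 with AG1478 and at 2.88, under background, untreated. At 48 h FSCN1, an actin-bundling protein, stood at 10.58 untreated and at 4.12, under background, with AG1478.

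Culture time in untreated cells, late against early, gave 0 genes in limma with Benjamini-Hochberg adjustment, 269 with an unadjusted p under 0.05 and a smallest adjusted p of 1. The unadjusted count depended on the fit, with 620 on only the 4 untreated arrays, 638 without the 24 h pair, 517 without the 48 h pair (where 3 genes passed), 127 without the 4 h pair and 78 without the 1 h pair, against 359 by chance. Among the values that did not pass were TP53I11, at least 3.90-fold higher, KCNC4, at least 2.91-fold higher, and DENND1B (-2.90 ± 1.01, with its untreated 24 h value under background). Camera gave the S phase list as lower (median -0.51, adjusted p = 0.0037; adjusted p = 0.59 with an estimated correlation) and the unfolded protein list as higher (median 0.29, adjusted p = 0.002; adjusted p = 0.59 with an estimated correlation).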

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

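The tests of the 24 h array and of the timing of mitosis genes were chosen after the results were seen, as was the exchange of labels within times; the count over splits of the arrays was planned.

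Array measures and the levels of named genes were checked within each arm of 4 arrays for a value far from the other 3, in 328 sets of values, and 31 stood out. Chance gives such a value in about 1 of 20 sets of normally distributed values, and over all tested genes 6.23% of 14356 sets held one. The gene levels checked here belong to genes named for large differences, so neither rate need hold for them. On the AG1478 24 h array the 3' to 5' ratios of ACTB (9.39) and GAPDH (5.69) and the spike-in signal (2796) stood out, with AKT2 (1.96, normalized log2 intensity), CCNG2 (2.62), ITGA6 (6.45) and RBL2 (2.58) low and MC1R (6.50) high. On the untreated 48 h array the 18S ribosomal RNA signal (1929), ADM (8.29) and S100A9 (7.47) were high, and ARHGAP19 (3.59), CCNB1 (7.58), MCM10 (4.42) and RRM2 (8.32) low. On the AG1478 48 h array AURKA (2.14), BUB1B (1.64), CCND1 (6.46), DPYSL3 (2.41), HLA-DQB1 (3.33), MFAP3L (2.39), SLC2A3 (3.79) and SPATA2L (2.65) were low. On the untreated 24 h array EVPL (3.23), ITGA2 (8.74), MYL9 (1.87) and PTGES (1.79) were low, on the untreated 4 h array AKT2 (2.37), FOS (3.88) and TMEM187 (2.23) were low, and on the untreated 1 h array ABCG1 (5.81) was high.

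The late and early effects differed for 40 genes in the contrast between them. The named ones, beyond those in the results, are S100A9 (4.08), SERPINB13 (3.90), SPRR1B (3.29), TGM2 (-4.91), ETV4 (-4.08), XDH (-3.30), LPXN (-3.22) and TSPAN1 (-2.96), beside CXCL14 (8.49), DSC1 (8.02), CRYAB (6.65), KRT13 (5.43), S100A8 (4.45), KRT16 (3.94), SPRR1A (3.81), TFPI2 (-6.27), DCBLD2 (-6.01), G0S2 (-5.47), MMP1 (-5.10) and HSP90B1 (-3.86). Values under background enter those of CXCL14, DSC1, CRYAB, KRT13, TFPI2, DCBLD2, TGM2, ETV4, G0S2, MMP1 and LPXN, which are therefore not exact sizes. Raising these values to background moved ETV4 to -1.76, TGM2 to -2.78 and CRYAB to 4.12, each over 1.5 times.

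The late gene group shifts were weighed against the 3' biased RNA of the AG1478 24 h array. Of 21 functional lists, 7, 7, 11 and 11 had a median outside the central 95% of matched random lists at 1, 4, 24 and 48 h, so this count alone sets the late times little apart from the early ones. The 11 lists outside at 24 h, picked without the 48 h arrays, had the same sign at 48 h in 11 cases and lay outside on the same side in 8, which argues against that array as the whole cause. Lists hold correlated genes, so 11 are not 11 independent results, and of the 7 lists outside at 1 h, 5 had the same sign at 4 h. It stays open for single 24 h differences: 68.4% of genes 2-fold different at 24 h kept their sign at 48 h, a share that neither excludes nor requires an effect of RNA quality. The 48 h pair has its own doubt, the ribosomal signal of the untreated array. An effect of AG1478 remains the hypothesis the design names, and array quality cannot be told apart from treatment for genes seen at 24 h alone.

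The G2 and mitosis list was lower at 48 h (median -1.49) with little difference at 24 h (-0.20). The 4 members named for the largest late differences lay under the background of the AG1478 48 h array (5.44, normalized log2 intensity). They were BUB1B (1.64), AURKA (2.14), TOP2A (2.82) and CCNB1 (4.94). How many other members did is not given here, so the size of the 48 h fall is uncertain. A damping of all responses alike on the AG1478 24 h array is argued against by the ERK feedback list, at -1.59 at 24 h and -1.58 at 48 h, and by the interferon list, at 1.40 and 1.08. Other lists were smaller at 24 h than at 48 h, the unfolded protein list at -0.68 and -1.56, the S phase list at -0.20 and -0.86 and the early differentiation list at 0.92 and 1.34, so damping of part of the responses stays open. A rise in untreated cells is argued against too, since their median for the mitosis list changed by -0.99 from 24 to 48 h, with 4 of 39 genes higher, while that of AG1478 cells changed by -1.88. A later loss of proliferation in inhibited cells is a hypothesis that was not tested here, and neither was RNA quality acting on these transcripts alone.

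Chance was examined with other groupings of the arrays. For the effect over all times, 32 of the 35 splits into 4 and 4 could be fitted, and the highest other gave 523. Since the real count was 0, all 32 gave as many genes whatever the data, so that comparison says nothing about chance. For genes at an unadjusted p under 0.05, 3 of 32 splits, the real included, gave at least the real 661, the highest other being 1734, so chance is not excluded. The highest ones set the late untreated against the late AG1478 arrays with whole early pairs on either side, so they hold the late treatment contrast itself, a structure of the samples and not chance alone. With time as a block, splits that keep whole pairs together give the same fit more than once. The highest other is such a fit, so the 32 are not all different. Among the 8 splits that part all 4 pairs, the highest other gave 396, but 8 are too few for a share under 0.05. For the late count, the 4 exchanges of labels within times are too few for a share under 0.05; the real labels gave 415, reached by 1 of the 4, the real one itself. The highest other, 279, exchanged the 4 h pair alone and kept the late labels, and the 2 that exchanged a late pair gave 0 genes each, with 266 and 252 at an unadjusted p under 0.05 in limma.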

How the results depend on the processing

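The fits with only the trend or only the robust setting were chosen after the data were seen. Precision is limited by the number of arrays and, for dim genes, by signal over background. Fits without 1 pair of arrays leave a lone pair in a phase, which is assumed to vary like the others. Among named genes and lists, 1461 late gene results under alternatives kept their direction and side of the threshold, 198 lost and 72 gained the call; for late minus early these were 227 kept and 89 lost, for early 345 kept and 21 gained, over all times 231 kept and 12 gained, for culture time 232 kept and 1 gained, and for late lists 154 kept, 25 lost and 5 gained. For each change below the cause was not tested, except that the fit with robust setting alone gave 0 late genes and the fit with trend alone 425, so the loss comes from leaving out the intensity trend.

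Over all times the count of 0 became 24 on arrays centred on their medians, 1 with a pseudocount of 16, 16 without a filter, 21 with array weights, 10 with no time block and 0 to 3 without a pair. The early count of 0 became 6 on centred arrays, 29 with array weights, 2 on phase means without the time block, and 0 to 34 without a pair. The late count of 415 became 0 in eBayes without trend and robust settings, 0 with robust alone, 243 with array weights and 300 to 1290 without a pair. On phase means without the time block it was 315, 298 of them shared. The late minus early count of 40 became 26 on centred arrays, 76 with a pseudocount of 16, 17 with the mean of probe sets, 0 without trend and robust settings, 0 with robust alone, 84 with array weights, 11 with a slope on log2 hours, 9 on phase means, and 16 to 685 without a pair. Culture time gave 0 to 3 without a pair. These zero counts come from limma, with 1328 and 1291 late and 712 and 691 late minus early genes at an unadjusted p under 0.05 without both settings and with robust alone.

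At 1, 4, 24 and 48 h, 3009, 2910, 4905 and 4553 genes differed 2-fold without a filter, 1642, 1702, 3672 and 3387 by 1.5-fold and 260, 211, 969 and 962 by 3-fold, as fewer or more genes enter. With an estimated correlation 0 lists were called late, 0 early and 0 over all times, against 12, 3 and 11, while fry called 0 early and 1 over all times. Without a pair, 3 to 12 lists were called over all times. Signs reversed, with no reversed value past the threshold, for early EGFR, at 0.66 with the mean of probe sets and -0.38 to 0.09 without a pair, and late KRT7, at 0.69 with the mean of probe sets, MC1R, at -0.01 on centred arrays and -0.57 to 0.62 without a pair, and AURKA, at -4.37 to 0.20 without a pair. AURKA at -4.37, without the 24 h pair, passed.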

Other observations

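The test of aryl hydrocarbon receptor targets below was chosen after the values were seen, as were the genes named in the next paragraph.

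Some late calls outside the fixed lists were picked one by one for their values, so they stand for no group. TAGLN (3.58 ± 0.55, log2, SE), MYLK (3.23 ± 0.42), PKP1 (2.0 ± 0.21), JUP (1.14 ± 0.26), DSP (0.92 ± 0.18), FGFR3 (2.18 ± 0.32) and EDN1 (3.98 ± 0.55) were higher. HYOU1 (-1.92 ± 0.21), CRELD2 (-1.82 ± 0.22), MANF (-1.66 ± 0.19), PDIA6 (-1.09 ± 0.17), CAD (-1.95 ± 0.33), HPRT1 (-1.75 ± 0.28), PNP (-1.93 ± 0.28), UPP1 (-2.14 ± 0.42), ODC1 (-2.07 ± 0.22), AXL (-2.36 ± 0.30), TGFBR2 (-2.03 ± 0.21) and VEGFC (-2.18 ± 0.39) were lower, and NRP1 was at least 5.01-fold lower. The sizes for EDN1 (untreated 24 h) and VEGFC (AG1478 48 h) rest on 1 dim array under background.

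CYP1A1 and CYP1B1, whose products metabolize aromatic compounds, were higher late, and at 4 h CYP1A1 stood at 7.69 with AG1478 and 2.88, under background, untreated. A candidate explanation is activity of the aryl hydrocarbon receptor, which induces both. None of its other targets tried passed the late test, with ALDH3A1 at 4.14 ± 1.08, NQO1 at -0.08 ± 0.25 and TIPARP at -0.67 ± 0.33, a median of -0.08. With only the 24 and 48 h arrays ALDH3A1 did pass (limma with Benjamini-Hochberg, adjusted p = 0.014), its untreated 24 h value being under background, so this stays open.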
